A study of Homo sapiens with 15 samples.

How the data were processed

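RNA-seq of 15 DLD1 libraries was analysed from 1 table of the whole series. Groups and replicate numbers come from the sample titles: WT, KO without doxycycline, and KO with doxycycline for 1, 3 or 9 days, with 3 libraries each. The labels call the replicates biological but do not state separate cultures, so p-values measure only the spread between these samples, which may be technical. WT cells given doxycycline were not analysed here.

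Per the submitters' processing notes, the authors aligned reads with HISAT2 2.1.0 to build hg19, counted them per gene with HTSeq and normalized them with DESeq2; the annotation, the strand setting and the versions of the last 2 tools are not given in the sources used here. The deposited values per library are normalized counts, a signal in which each library's counts are divided by its size factor. Per the file headers the authors also give group means, log2 fold changes against KO and adjusted p-values for 4 comparisons; these deposited log2 and p-value columns were used only for the comparison with the authors' calls. All values of a library were whole multiples of 1 step (0.99 to 1.007, within a tolerance of 1e-06). Total normalized counts ran from 14741459 to 15347353 per library, and the top 10 genes took 4.748 to 5.377% of them. Column names carry 1 project code for 9 libraries and another for 6 (days 3 and 9). Of 22706 genes, 22463 have a symbol, paired by Ensembl ID from a separate reference of gene names, and 1 was left out for a cell holding text.

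From these values log2(value + 1) was computed, genes with a value of at least 10 in at least 3 libraries were kept (15134), and limma 3.58.1 (statmod 1.5.0, R 4.3.3) was fitted to all 15 libraries with 1 mean per group and eBayes with trend and robust options. Adjusted p is Benjamini-Hochberg, threshold 0.05, two-sided. The planned design named a count test if the table held counts. The table holds normalized values, which were not used as reads in any test because steps this close to 1 were treated as rounding. The fit planned for normalized values was therefore used. The median standard error of a log2 fold change was 0.087. Tested on simulated data for KO against WT with 15134 genes, the fit recovered 34 of 50 genes changed 1.25-fold and 42 of 50 at 1.5-fold. It recovered 50 of 50 at both 2-fold and 4-fold, and called 15 of 14934 unchanged genes, 7.9% of its calls. The simulation changed far fewer genes than the 7519 called in the data, all with a mean of at least 50. Its rates need not hold for the real fit.

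Gene lists (34) were written before the data were examined, as were the design, the other settings and the rule for named genes. Lists with at least 5 tested members (30) were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. The marker lists for leukocytes, fibroblasts, endothelial cells and neural or kidney lines had fewer than 5 tested members and were not tested; 8, 4, 4 and 4 of their genes were in the table. The results of 1 tested list and of some genes are not reported here. Named genes are, for KO against WT and day 9 against KO, the 10 largest changes in each direction among genes past the threshold with a mean of at least 50 and no overlap between the groups; for day 1 and day 3 against KO and day 9 against WT the 5 largest; up to 4 members per list with the lowest adjusted p; members of the PRC1 and PRC2 lists; and for reversal the 5 largest knockout changes in each direction, a rule applied at day 1 only after the data were seen.

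Reversal was counted as genes past the threshold in KO against WT and past it with the opposite sign against KO. The recovered share is (dox - KO)/(WT - KO) on the log2 scale, with genes and denominators taken without the KO library that serves as baseline, for each KO library in turn. Replicate pairs were compared by Pearson r across genes (0.9908 to 0.9957; genes are not independent) and by the ratio of their difference to counting noise (1.15 to 10.86), and none was a duplicate. Alternatives covered scaling to equal medians, filters, pseudocounts, fewer libraries in the fit, each library left out, a replicate block and the authors' calls. Figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.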

Results

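RNA-seq was measured in DLD1, a human colorectal cancer cell line, in 15 libraries that fall into 5 groups of 3. Parental cells (WT) were set beside a USP7 knockout line (KO) in which doxycycline switches on a GFP-tagged USP7. The KO cells were grown without doxycycline or with it, at 1 µg/ml, for 1, 3 or 9 days. USP7 is a deubiquitinase that removes ubiquitin from the E3 ligase MDM2 and components of Polycomb complexes, among other proteins. Poly(A) RNA was sequenced with a strand-marking kit. Total normalized counts per library lay between 14741459 (day 9, replicate 3) and 15347353 (KO, replicate 1), and 20858 to 21315 genes were above 0. The WT, KO and day 1 libraries (9) carried 1 project code in the deposited table, and the day 3 and day 9 libraries (6) carried another. Every mean below is in normalized counts ± SD with n = 3. Fold changes are log2 differences of value + 1, which understate changes of low genes, and adjusted p values are from limma with Benjamini-Hochberg adjustment over 15134 genes.

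USP7 (ENSG00000187555) followed the labels in every group. Its transcript stood at 3391.8 ± 25.4 in WT cells and 1389.3 ± 17.6 in KO cells, a log2 change of -1.29 (SE 0.05, adjusted p = 8.95e-15), so USP7 transcript was still measured in KO cells without doxycycline. One day of doxycycline brought it to 8238.9 ± 375.3, which was 2.57 log2 units above KO (adjusted p = 4.74e-19) and 1.28 above WT (adjusted p = 1.31e-14). The level was 7827.9 ± 341.2 at day 3 and 4787.9 ± 335.7 at day 9. USP7 fell by 0.71 log2 units between day 3 and day 9 (adjusted p = 5.91e-09) and at day 9 still stood 0.49 above WT (adjusted p = 2.73e-07). The counts do not separate transgene from endogenous transcript.

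**Figure D1:**
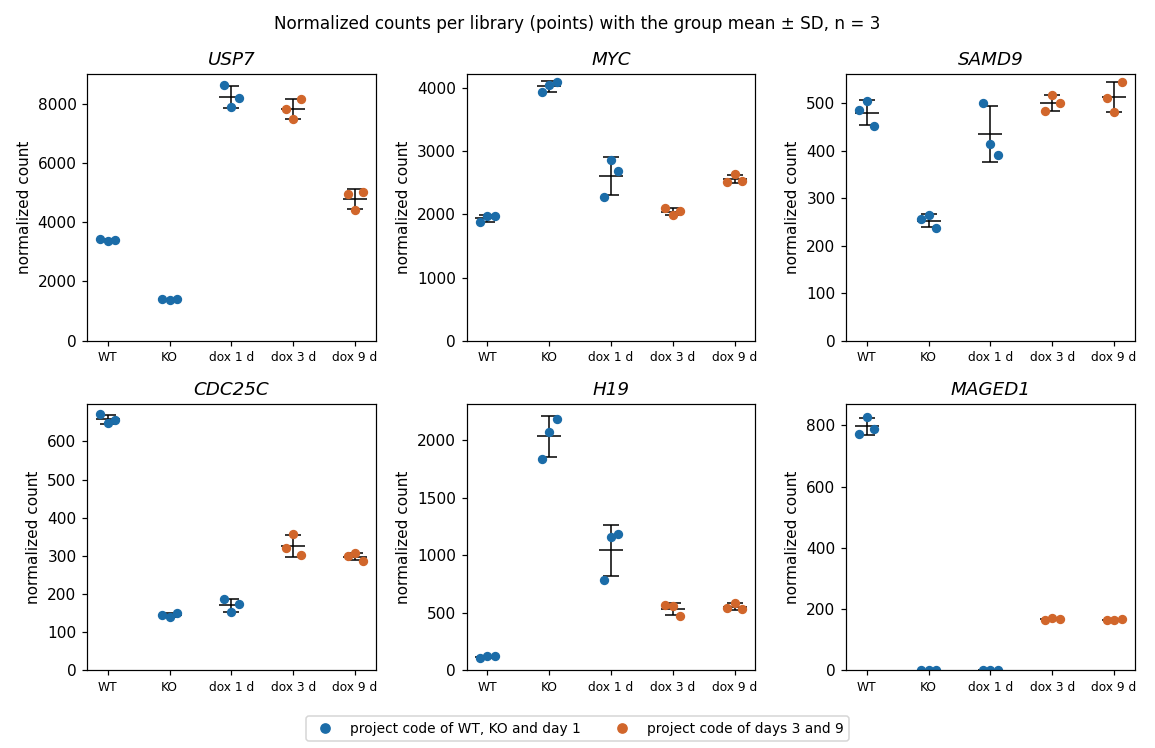
Normalized counts (vertical axis, from 0) of USP7, MYC, SAMD9, CDC25C, H19 and MAGED1 in each of the 15 libraries (points), by group (horizontal axis), with bars for the mean ± SD, n = 3, where blue points carry the project code of WT, KO and day 1, orange points that of days 3 and 9. MYC stood at 1941.1 in WT, 4027.6 in KO and 2605.3 at day 1, and MAGED1 was listed at 0 in the KO and day 1 libraries.

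The comparison of KO with WT asked what differs between the knockout line and its parental cells. The KO line also carries the inducible transgene, so USP7 loss cannot be told apart here from other differences between the lines. The knockout effect or change named below means this difference. Largest changes are named here and below among genes with a mean of at least 50 over the groups compared and no overlap between their libraries. The largest increases included SULF2, which encodes an extracellular heparan sulfate sulfatase and rose from 48.5 ± 3.1 to 966.8 ± 34.2 (log2 change 4.29, SE 0.07, adjusted p = 2.2e-20). The gastric mucin MUC6 went from 25.2 ± 9.2 to 479.9 ± 17.2 (4.25). The imprinted non-coding RNA H19 rose from 117.0 ± 8.1 to 2034.8 ± 176.2 (4.11) and the intestinal galectin LGALS4 from 23.6 ± 1.5 to 412.2 ± 31.2 (4.07). The anti-apoptotic gene BCL2 rose from 28.2 ± 4.2 to 305.0 ± 6.5 (3.40, adjusted p = 1.43e-14). The chromatin organizer SATB1 rose from 93.4 ± 1.9 to 850.0 ± 34.4 (3.17) and RAMP1, KRT13, PSCA and FER1L6 by 2.98 to 3.53 log2 units. The 10 largest decreases within this limit were of genes listed at 0 in all 3 KO libraries. Among them were MAGED1 (796.1 ± 29.1 in WT), the potassium channel gene KCNJ5 (599.1 ± 22.1), WDR76 (489.5 ± 27.5), SPIN3 (440.9 ± 20.2) and the YAP partner TEAD2 (375.5 ± 15). The others were TSPOAP1 (336.6 ± 2.4), ZNF680 (329.3 ± 12.5), ZNF780B (308.4 ± 13.3), NME4 (279.8 ± 31.6) and the myosin light chain kinase gene MYLK (269.2 ± 15.8). In all, 7519 of 15134 genes passed, 3759 higher and 3760 lower in KO, and 1319 of them changed by at least 1 log2 unit (553 higher, 766 lower). The authors' deposited table passes 6589 genes at the same threshold. Of these, 6314 of the 6343 that were also tested here passed here with the same sign.

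Mitotic genes were lower in KO cells, where 40 of the 42 tested fell (40 adjusted over the list alone, median log2 change -0.45, camera adjusted p = 1.62e-17). The list did not pass at adjusted p = 0.104 with an estimated correlation. CDC25C, the phosphatase that activates CDK1, fell from 658.2 ± 12.4 to 144.7 ± 4.5 (-2.18, adjusted p = 8.95e-15). The spindle gene ASPM fell from 2963.3 ± 148.1 to 1215.4 ± 22.7, TOP2A from 15901.1 ± 557.1 to 8384.5 ± 100.4 and UBE2C from 1560.3 ± 28.7 to 967.2 ± 26.5. MYC targets and ribosome biogenesis genes moved the other way. Of 43, 37 rose and 1 fell (38 and 1 adjusted over the list alone, median 0.32, adjusted p = 2.38e-10, and adjusted p = 0.0242 with an estimated correlation). MYC itself rose from 1941.1 ± 57.6 to 4027.6 ± 83.6 (1.05, adjusted p = 7.67e-12). The spermidine synthase SRM rose from 1087.9 ± 35.5 to 1903.5 ± 131.4 and the nucleolar protein gene FBL from 2675.4 ± 18.8 to 3788.4 ± 90.0. Interferon response genes were lower, 20 of 34 with 2 higher (20 and 2 adjusted over the list alone, median -0.32, adjusted p = 0.000589, and adjusted p = 0.0242 with an estimated correlation). HERC5 stood at 119.6 ± 8.1 in WT and 2.3 ± 0.6 in KO. MX2 fell from 101.7 ± 7.1 to 18.9 ± 4.3 and IFIT3 from 99.0 ± 9.1 to 30.2 ± 1.5.

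The lists of cytosolic and mitochondrial ribosomal proteins, the unfolded protein response and nuclear oxidative phosphorylation were higher in KO by smaller amounts, and those of heat shock and mtDNA-encoded genes did not pass. Of 73 cytosolic ribosomal protein genes, 48 rose and 2 fell (51 and 2 adjusted over the list alone, median 0.21, camera adjusted p = 1.61e-09, adjusted p = 0.299 with an estimated correlation). RPL38 rose from 5407.3 ± 58.0 to 8267.7 ± 183.0. The unfolded protein response list had 19 of 25 higher and 1 lower (19 and 1 adjusted over the list alone, 0.25, adjusted p = 5.88e-05, adjusted p = 0.0592 with an estimated correlation). The chaperones CALR and HSPA5 rose, CALR from 13618.8 ± 82.5 to 20070.9 ± 530.4 and HSPA5 from 9679.6 ± 78.1 to 13551.9 ± 209.7. Nuclear-encoded oxidative phosphorylation genes rose in 23 of 42 cases and fell in 1 (24 and 1 adjusted over the list alone, median 0.16, adjusted p = 0.000589, adjusted p = 0.315 with an estimated correlation). Of 45 mitochondrial ribosomal proteins, 21 rose and 2 fell (22 and 2 adjusted over the list alone, median 0.16, adjusted p = 0.000983, adjusted p = 0.299 with an estimated correlation). MRPS9 rose from 1014.8 ± 15.3 to 1992.7 ± 36.3. Ribosomal protein and histone genes have near-identical copies and pseudogenes, so their single values are less certain than those of other lists. Poly(A) RNA was sequenced, so histone changes here and below are of polyadenylated transcripts and need not hold for histone mRNA as a whole.

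Developmental transcription factors that are typical Polycomb targets were higher as a list. Of 41, 29 rose and 5 fell (29 and 5 adjusted over the list alone, median 0.43, adjusted p = 0.000937, adjusted p = 0.315 with an estimated correlation). PROX1 rose from 201.0 ± 16.3 to 384.3 ± 8.7 and OTX1 from 129.3 ± 3.7 to 264.5 ± 9.3, while RUNX2 fell from 1594.9 ± 17.4 to 1087.6 ± 62.7. Among 40 subunits of PRC1 and its non-canonical forms, which ubiquitinate histone H2A, 15 rose and 8 fell (16 and 8 adjusted over the list alone, median 0.07, adjusted p = 0.367). The ncPRC1 component AUTS2 changed most, from 31.2 ± 3.6 to 234.3 ± 13.9 (2.87, adjusted p = 3.14e-13), BCORL1 rose from 317.3 ± 7.3 to 549.3 ± 46.0 and DCAF7 fell from 3977.3 ± 74.0 to 2873.6 ± 32.1. PRC2 subunits and partners went both ways, 4 of 14 in each direction (median -0.01, mean 0.02, adjusted p = 0.993). JARID2 rose from 289.4 ± 8.9 to 535.7 ± 9.1 and PHF19 fell from 1949.8 ± 32.4 to 1173.9 ± 40.1. The HOX genes also split, 9 of 27 higher and 7 lower (median 0.04, adjusted p = 0.987), with HOXB4 up from 839.0 ± 55.3 to 1532.3 ± 103.2 beside HOXB5 down from 582.8 ± 17.6 to 249.6 ± 23.3. H2A deubiquitinases (3 of 15 higher, 4 lower, adjusted p = 0.706) and germline genes typical of PRC1.6 targets (1 of 14 higher, 6 lower, adjusted p = 0.253) did not pass as lists.

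Other lists held strong single changes without passing as lists. The intestinal differentiation list had 17 of 29 genes higher and 10 lower (median 0.53, adjusted p = 0.0655, and 0.0464 without WT replicate 3 and 0.0491 without KO replicate 1). The microvillus gene VIL1 rose from 539.2 ± 19.3 to 2097.2 ± 163.7 and MUC13 fell from 887.5 ± 50.2 to 443.4 ± 28.9. Of 28 Wnt targets 12 rose and 8 fell (adjusted p = 0.367), and LGR5, the intestinal stem cell marker, fell from 1268.3 ± 10.4 to 223.0 ± 18.9 (-2.51). Of 18 mesenchymal genes 9 fell and 5 rose (median -0.44, adjusted p = 0.188). Tenascin C (TNC) stood at 656.9 ± 16.8 in WT and 33.2 ± 5.1 in KO, whereas SNAI1 rose from 47.8 ± 2.1 to 141.7 ± 16.8. USP7 partners and substrates did not pass (8 of 35 higher, 12 lower, median 0.01, mean -0.26, adjusted p = 0.557). Nor did E2F targets (13 of 48 higher, 9 lower, 0.438) or the integrated stress response (16 of 34 higher, 5 lower, 0.0759, and 0.021 without KO replicate 2). Hypoxia and glycolysis (9 of 33 higher, 15 lower, 0.36), NF-kB genes (4 of 16 higher, 5 lower, 0.845), YAP targets (6 of 20 higher, 7 lower, 0.438) and FOXO targets (8 of 18 higher, 7 lower, median -0.13, mean 0.02) did not pass either. The same held for immediate early genes (9 of 30 higher, 10 lower, 0.906), replication-dependent histones (6 of 14 higher, 3 lower, 0.367) and mtDNA-encoded genes (2 of 13 higher, 4 lower, 0.475), each value in parentheses being the camera adjusted p.

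**Figure D2:**
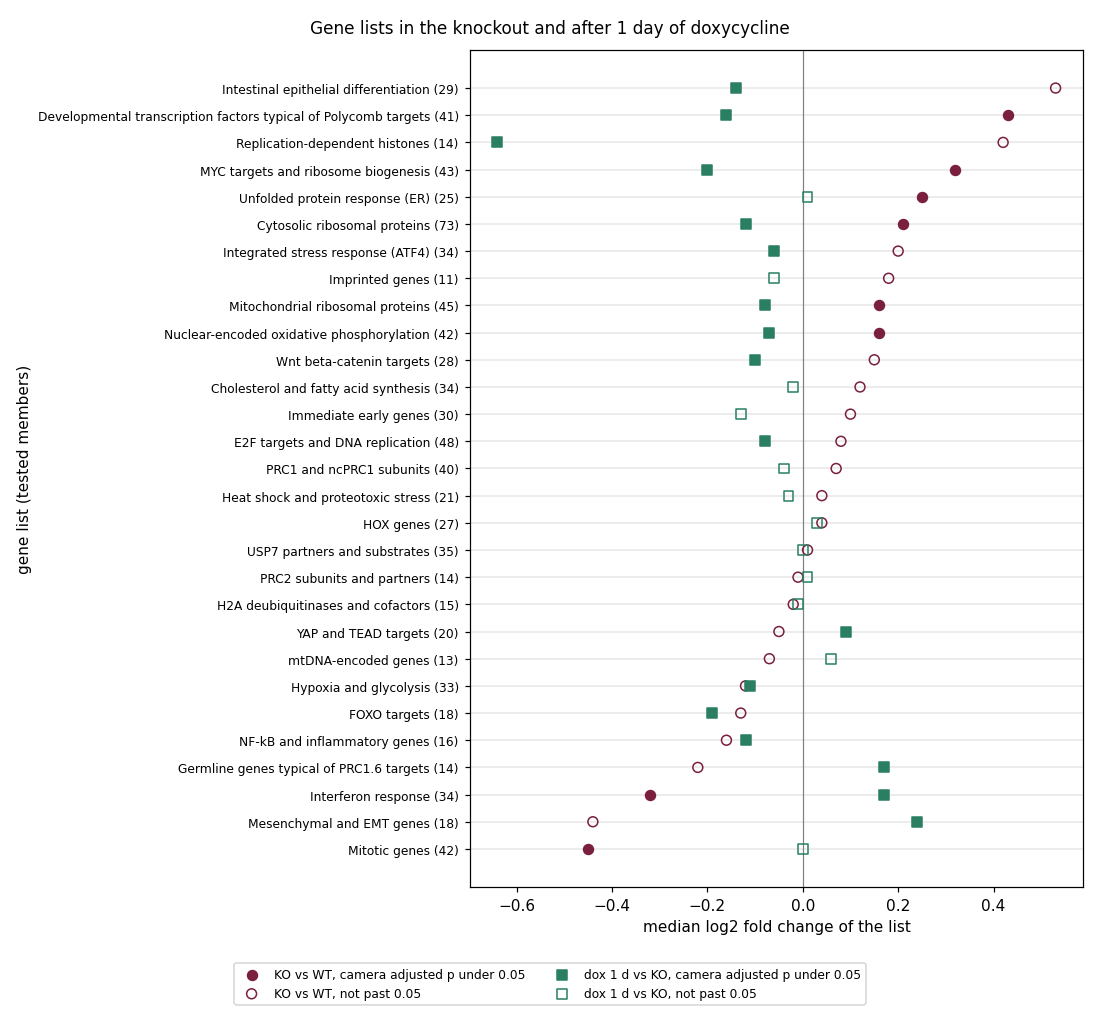
Median log2 fold change (horizontal axis) of gene lists with at least 5 tested members (vertical axis, number tested in parentheses), for KO against WT (circles) and 1 day of doxycycline against KO (squares), where filled symbols passed camera at an adjusted p under 0.05, and no error bars are drawn. Mitotic genes stood at -0.45 in KO against WT and 0 at day 1 against KO, MYC targets at 0.32 and -0.2.

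The comparison of day 1 with KO asked what 1 day of USP7 re-expression changes. After USP7 itself, the largest increases within the limit of a mean of at least 50 included GSDMA, which encodes a gasdermin pore protein and rose from 125.1 ± 0.6 to 367.0 ± 15.7 (log2 change 1.54, adjusted p = 8.13e-11), and RUFY3 (624.3 ± 29.9 to 1568.8 ± 170.3, 1.32). The retinal reductase DHRS3 (73.7 ± 17.7 to 174.2 ± 50.7, 1.21) and INTS6L-AS1 (23.2 ± 2.1 to 91.5 ± 19.6, 1.92) rose too. INTS6L-AS1 lies antisense to INTS6L (6.6 ± 3.2 to 18.4 ± 4.5), and since the strand setting of the counting is not given in the sources used here, reads of this pair cannot be told apart. BCL2 fell from 305.0 ± 6.5 to 101.2 ± 13.1 (-1.59, adjusted p = 1.74e-07), KRT13 from 96.6 ± 19.9 to 27.0 ± 6.0 (-1.80) and the clock-related repressor BHLHE41 from 74.7 ± 10.4 to 28.1 ± 7.1 (-1.40). The histone gene H2BC21 fell from 106.9 ± 15.8 to 27.7 ± 10.3 (-1.97) and H2AC6 from 186.5 ± 22.5 to 71.1 ± 14.8 (-1.39). Altogether 1650 genes passed, 747 higher and 903 lower (45.3% higher, 49.6% after scaling to equal medians), of which 121 changed by at least 1 log2 unit. Day 1 replicate 1 stood apart from the other libraries of its group: the variance of its difference from replicates 2 and 3 was 10.86 and 7.2 times that of counting alone, against 1.37 between replicates 2 and 3. The count was 984, 958 and 1058 without KO replicate 1, 2 and 3, 1096 without day 1 replicate 3, and 2418 without day 1 replicate 1. Fitting only the 6 libraries compared gave 613.

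MYC targets and ribosome biogenesis genes fell within 1 day, 24 of 43 (34 adjusted over the list alone, median -0.2, camera adjusted p = 8.02e-17, and adjusted p = 0.0037 with an estimated correlation). MYC went from 4027.6 ± 83.6 to 2605.3 ± 301.2 (-0.63, adjusted p = 8.64e-07), SRM from 1903.5 ± 131.4 to 1360.9 ± 112.0 and NOP16 from 909.4 ± 15.3 to 696.6 ± 13.6. Interferon response genes rose, 10 of 34 (15 adjusted over the list alone, median 0.17, adjusted p = 3.6e-08, and adjusted p = 0.00141 with an estimated correlation). SAMD9 stood at 252.9 ± 14.4 and 435.7 ± 58.2 (0.78), IFIT1 at 58.1 ± 5.0 and 104.9 ± 16.8 and MX2 at 18.9 ± 4.3 and 44.1 ± 7.1. Mesenchymal genes rose as well, 5 of 18 (6 adjusted over the list alone, median 0.24, adjusted p = 0.00191, and adjusted p = 0.0424 with an estimated correlation). TNC reached 69.5 ± 9.1 from 33.2 ± 5.1 and TGFBI 1956.0 ± 39.0 from 1655.5 ± 44.0. Mitotic genes had not moved past the threshold at this time (median 0, adjusted p = 0.792). CDC25C stood at 144.7 ± 4.5 and 170.7 ± 17.2 (adjusted p = 0.076).

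Another 14 lists passed camera at day 1 and none of these did with an estimated correlation. Cytosolic ribosomal proteins fell, 20 of 73 (32 adjusted over the list alone, median -0.12, adjusted p = 6.74e-12, adjusted p = 0.223 with an estimated correlation). Replication-dependent histones fell in these poly(A) libraries, 4 of 14 (8 adjusted over the list alone, median -0.64, adjusted p = 0.00053, adjusted p = 0.283 with an estimated correlation). Hypoxia and glycolysis genes had 7 of 33 lower and 2 higher (11 and 3 adjusted over the list alone, adjusted p = 0.00048, adjusted p = 0.295 with an estimated correlation). PFKFB3, an activator of glycolysis, fell from 1188.5 ± 68.1 to 729.4 ± 91.4 while PKM rose from 35587.0 ± 505.8 to 44304.8 ± 2135.2. Nuclear oxidative phosphorylation shifted down by a small amount (median -0.07, adjusted p = 0.00177, 1 member higher and 1 lower, adjusted p = 0.295 with an estimated correlation). Mitochondrial ribosomal proteins did too (4 of 45 lower, median -0.08, adjusted p = 0.00125, adjusted p = 0.254 with an estimated correlation). The mtDNA-encoded genes did not pass (median 0.06, adjusted p = 0.33). The calls of the other 9 lists ended when 1 library was left out. Developmental transcription factors (7 of 41 lower, adjusted p = 0.00525, adjusted p = 0.295 with an estimated correlation) reached 0.178 without day 1 replicate 1. Wnt targets (7 of 28 lower, 1 higher, adjusted p = 0.00053, adjusted p = 0.295 with an estimated correlation) reached 0.0768 without that library. E2F targets (4 of 48 lower, adjusted p = 0.00167, adjusted p = 0.387 with an estimated correlation) reached 0.051 without day 1 replicate 2. YAP targets (5 of 20 higher, 2 lower, median 0.09, mean 0, adjusted p = 0.0375, adjusted p = 0.295 with an estimated correlation) reached 0.0978 without day 1 replicate 2 and 0.0908 without KO replicate 2. The FOXO list (3 of 18 lower, 1 higher, adjusted p = 0.0375, adjusted p = 0.295 with an estimated correlation) reached 0.123 without KO replicate 3 and 0.159 without day 1 replicate 1. The integrated stress response (2 of 34 lower, adjusted p = 0.0165, adjusted p = 0.464 with an estimated correlation) reached 0.21 and 0.178 without the same libraries. Intestinal differentiation (5 of 29 lower, 1 higher, adjusted p = 0.0452, adjusted p = 0.295 with an estimated correlation) reached 0.0741, 0.0786 and 0.19 without KO replicate 2, KO replicate 3 and day 1 replicate 1. NF-kB genes (2 of 16 lower, adjusted p = 0.0427, adjusted p = 0.223 with an estimated correlation) reached 0.0637, 0.0552 and 0.178 without KO replicate 1, KO replicate 3 and day 1 replicate 1. Germline genes (2 of 14 higher, adjusted p = 0.0464, adjusted p = 0.254 with an estimated correlation) reached 0.168, 0.141 and 0.0847 without KO replicate 2, day 1 replicate 1 and day 1 replicate 2. The number of lists that passed was 17, and 10 without day 1 replicate 1.

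At day 1 most of the knockout difference from WT was still present, as asked by comparing day 1 with WT. LGR5 stood at 312.6 ± 12.3 against 1268.3 ± 10.4 in WT (-2.02, adjusted p = 1.49e-15), VIL1 at 2131.2 ± 105.9 against 539.2 ± 19.3 (1.98) and CDC25C at 170.7 ± 17.2 against 658.2 ± 12.4 (-1.95). SAMD9 (435.7 ± 58.2 against 480.8 ± 27.2) no longer passed, with an adjusted p of 0.159. In all 6158 genes passed, 3012 higher and 3146 lower than WT (48.9% higher, 52.9% after scaling to equal medians). Mitotic genes were lower, 41 of 42 (median -0.45, camera adjusted p = 7.19e-21, adjusted p = 0.13 with an estimated correlation). Unfolded protein response genes were higher, 19 of 25 (median 0.23, adjusted p = 1.13e-06, adjusted p = 0.0559 with an estimated correlation). MYC targets were higher, 18 of 43 with 2 lower (median 0.13, adjusted p = 0.00212, adjusted p = 0.434 with an estimated correlation). So were cytosolic ribosomal proteins, 33 of 73 with 5 lower (adjusted p = 0.00212, adjusted p = 0.688 with an estimated correlation), and developmental factors, 15 of 41 with 6 lower (adjusted p = 0.0293, adjusted p = 0.688 with an estimated correlation). Hypoxia and glycolysis genes were lower, 20 of 33 with 4 higher (adjusted p = 0.00287, adjusted p = 0.688 with an estimated correlation).

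The day 3 and day 9 libraries differ from the other 9 in project code, so code and time of treatment cannot be told apart in any comparison of these 2 groups with WT, KO or day 1. One feature of their values stood out in genes that were all but silent in KO. There were 59 genes with a KO mean under 2% of a WT mean over 50. At day 1 their median was 0% of WT, and TSPOAP1 alone exceeded 5% (56.1 ± 12.9 against 336.6 ± 2.4 in WT). At days 3 and 9, 51 of the 59 were above 0 at a median of 22.4% of WT, with 20.4% the lowest and 40.7% the highest gene, and per-library medians between 21.6% and 22.5%. The other 8, including SH3BGRL (220.0 ± 19.8 in WT) and GABRE (132.9 ± 12.7), were listed at 0 in all 6 libraries. The within-group variance of the 51 genes was 0.33 times their mean (95% bootstrap interval 0.21 to 0.49), where genes of the same level had 0.93 in WT, 0.91 in KO and 1.35 to 1.55 in the doxycycline groups.

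**Figure D3:**
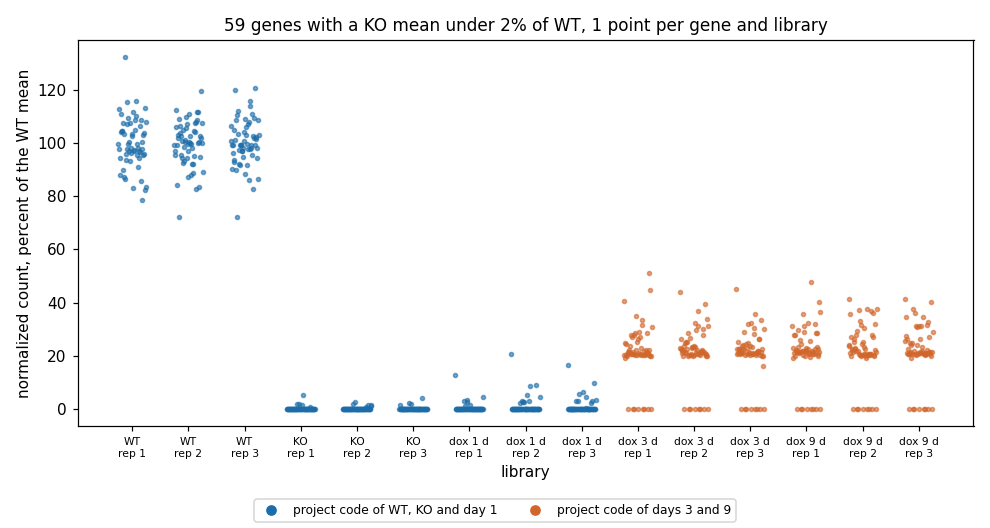
Normalized count as a percent of the WT mean (vertical axis) for the 59 genes with a KO mean under 2% of WT, 1 point per gene and library, in the 15 libraries (horizontal axis), where blue points carry the project code of WT, KO and day 1, orange points that of days 3 and 9, and no error bars are drawn. At days 3 and 9, 51 genes lie at a median of 22.4% of WT and 8 at 0.

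In the day 3 and day 9 libraries, which carry the other project code, some genes lowered in KO, such as TNC, stood higher than in KO and some raised in KO, such as KRT13, stood lower. TNC rose from 33.2 ± 5.1 to 190.9 ± 12.5 at day 3 and 311.5 ± 8.9 at day 9 (log2 change 3.20, adjusted p = 5.2e-15). The actin crosslinker FLNA rose from 735.8 ± 84.8 to 5367.9 ± 134.2 and 5656.4 ± 374.2 and QPCT from between 38.8 and 76.7 in the KO libraries to 510.6 ± 24.8 and 554.0 ± 26.5. KLHL4 rose from 42.5 ± 3.1 to 303.8 ± 33.5 and 291.2 ± 28.7, and the transcription factor TCF4 from 19.6 ± 2.1 to 129.7 ± 21.6 and 117.6 ± 4.2. MAGED1, KCNJ5, WDR76, TEAD2 and TSPOAP1, all listed at 0 in the 3 KO libraries, had the largest fitted increases at day 9 among genes with a mean of at least 50, but they belong to the 51 silent genes described above. MAGED1 stood at 167.1 ± 2.8 and 165.3 ± 1.8 and KCNJ5 at 131.7 ± 6.1 and 156.4 ± 9.7. KRT13 fell from 96.6 ± 19.9 to 10.6 ± 1.2 and 4.6 ± 1.2 (-4.11 at day 9), BCL2 from 305.0 ± 6.5 to 56.6 ± 1.7 and 45.7 ± 4.6 (-2.72). The water channel AQP3 fell from 1035.8 ± 62.7 to 503.6 ± 13 and 233.9 ± 15.6 (-2.14) and H19 from 2034.8 ± 176.2 to 534.7 ± 52.3 and 554.3 ± 31.0. SULF2 fell from 966.8 ± 34.2 to 354.8 ± 16.6 and 264.4 ± 9.0 and AUTS2 from 234.3 ± 13.9 to 100.3 ± 8.3 and 63.6 ± 7.9. MUC6, LGALS4, PSCA, KRT4 and H2BC21 were also among the largest decreases at 1 or both times. At day 3, 4149 genes passed (2039 higher, 2110 lower), and at day 9, 3915 (1884 higher, 2031 lower).

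Cytosolic ribosomal proteins fell at both times in these libraries of the other project code, 60 of 73 at day 3 (65 adjusted over the list alone, median -0.24, camera adjusted p = 2.47e-24, and adjusted p = 0.0436 with an estimated correlation). At day 9, 48 fell (57 adjusted over the list alone, -0.19, 1.23e-17, adjusted p = 0.105 with an estimated correlation). MYC targets fell, 30 of 43 at day 3 (35 adjusted over the list alone, -0.21, 1.48e-11, and adjusted p = 0.0164 with an estimated correlation). At day 9 27 fell (29 adjusted over the list alone, -0.18, 4.75e-09, and adjusted p = 0.0382 with an estimated correlation), and MYC stood at 2043.0 ± 55.9 and 2558.1 ± 66.4. Interferon genes rose, 21 of 34 with 1 lower at day 3 (21 and 1 adjusted over the list alone, 0.28, 1.22e-06, and adjusted p = 0.00399 with an estimated correlation). At day 9 19 rose (20 adjusted over the list alone, 0.27, 3.78e-07, and adjusted p = 0.00252 with an estimated correlation). SAMD9 reached 500.7 ± 17.4 and 513.3 ± 31.8, while HERC5 (33.1 ± 7.4 and 36.4 ± 1.5) is 1 of the 51 silent genes at 20.4 to 40.7% of WT. Mitotic genes rose, 23 of 42 at day 3 (27 adjusted over the list alone, 0.19, 2.68e-09, adjusted p = 0.261 with an estimated correlation). At day 9 16 rose (17 adjusted over the list alone, 0.13, 4.36e-05, adjusted p = 0.309 with an estimated correlation), with CDC25C at 326.9 ± 28.9 and 298.2 ± 10.0. YAP targets were higher, 13 of 20 with 2 lower at day 3 (14 and 2 adjusted over the list alone, 0.22, 6.36e-07, and adjusted p = 0.0216 with an estimated correlation). At day 9 11 were higher and 2 lower (11 and 4 adjusted over the list alone, 0.14, 0.00236, adjusted p = 0.111 with an estimated correlation). CCN1, a matricellular YAP target, stood at 516.4 ± 6.3 in KO, 926.6 ± 12.8 and 831.7 ± 28.1.

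Developmental transcription factors fell with the same change of code, 16 of 41 with 4 higher at day 3 (camera adjusted p = 0.000639, adjusted p = 0.27 with an estimated correlation). At day 9 17 were lower and 4 higher (0.000314, adjusted p = 0.245 with an estimated correlation), PROX1 standing at 216.8 ± 17.2 and 233.6 ± 6.0. Nuclear oxidative phosphorylation fell at both times, 12 of 42 at each (0.000405 and 0.000314, adjusted p = 0.27 and 0.245 with an estimated correlation). So did histones, 6 of 14 at each (0.00101 and 0.00807, adjusted p = 0.27 and 0.309 with an estimated correlation). Mitochondrial ribosomal proteins fell, 11 of 45 at day 3 (0.000503, adjusted p = 0.236 with an estimated correlation) and 5 at day 9 (0.0185, adjusted p = 0.309 with an estimated correlation). The day 9 call ended at 0.086 without KO replicate 1. At day 3, Wnt targets were lower (14 of 28, 3 higher, 0.000523, adjusted p = 0.32 with an estimated correlation). Cholesterol synthesis genes were higher (12 of 34, 1 lower, 0.00432, adjusted p = 0.236 with an estimated correlation). Integrated stress response genes were lower (9 of 34, 0.00764, adjusted p = 0.364 with an estimated correlation, 0.0842 without KO replicate 3 and 0.0671 without day 3 replicate 3). At day 9, intestinal differentiation genes were lower (14 of 29, 4 higher, 0.000116, adjusted p = 0.105 with an estimated correlation). KRT18 went from 45846.6 ± 1124.3 to 28288.6 ± 1358.0. Mesenchymal genes were higher (7 of 18, 2 lower, 0.0231, adjusted p = 0.105 with an estimated correlation) and unfolded protein response genes lower (7 of 25, 2 higher, 0.0185, adjusted p = 0.226 with an estimated correlation). FOXO targets were lower (7 of 18, 1 higher, 0.0219, adjusted p = 0.309 with an estimated correlation) and NF-kB genes lower (6 of 16, 1 higher, 0.0231, adjusted p = 0.105 with an estimated correlation, 0.0522 without day 9 replicate 1). The lists of PRC1 (adjusted p = 0.231 and 0.35), PRC2 (0.638 and 0.868) and HOX genes (0.897 and 0.306) did not pass at days 3 and 9.

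At day 9 many genes still stood apart from WT, again across the 2 project codes. MUC6 (204.4 ± 9.8 against 25.2 ± 9.2 in WT, log2 change 3.02, adjusted p = 3.65e-09), SATB1 (518.2 ± 43.4 against 93.4 ± 1.9, 2.46) and SULF2 (264.4 ± 9.0 against 48.5 ± 3.1, 2.42) had the largest excess among genes with a mean of at least 50 over the 2 groups. LGALS4 (119.3 ± 20.6 against 23.6 ± 1.5, 2.28) and H19 (554.3 ± 31.0 against 117.0 ± 8.1, 2.24) followed. SH3BGRL and GABRE, at 0 in all 12 KO and doxycycline libraries, KRT20 (39.4 ± 2.1 against 197.7 ± 29.8), MAGED1 (165.3 ± 1.8 against 796.1 ± 29.1) and CGREF1 (31.8 ± 0.1 against 155.8 ± 7.8) had the largest deficits within the same limit, and all 5 are among the 59 silent genes. KRT20 lost its call at a pseudocount of 0.1. Mitotic genes were lower, 38 of 42 (39 adjusted over the list alone, median -0.33, camera adjusted p = 2.58e-26, adjusted p = 0.0661 with an estimated correlation). Of 43 MYC targets 16 were higher and 1 lower (18 and 1 adjusted over the list alone, 0.14, 3.1e-06, adjusted p = 0.0806 with an estimated correlation). Unfolded protein response genes (12 of 25, 14 adjusted over the list alone, 6.92e-06, adjusted p = 0.0661 with an estimated correlation) and integrated stress response genes (15 of 34, 2 lower, 19 and 2 adjusted over the list alone, 6.92e-06, adjusted p = 0.366 with an estimated correlation) were higher. So were cholesterol synthesis genes (14 of 34, 3 lower, 0.000828, adjusted p = 0.124 with an estimated correlation) and mitochondrial ribosomal proteins (8 of 45, 0.0082, adjusted p = 0.421 with an estimated correlation). Hypoxia genes (14 of 33, 3 higher, 0.000219, adjusted p = 0.554 with an estimated correlation) and NF-kB genes (8 of 16, 3 higher, 0.0273, adjusted p = 0.123 with an estimated correlation) were lower. Interferon genes (3 of 34 higher, 7 lower, adjusted p = 0.435) and cytosolic ribosomal proteins (6 of 73 higher, 2 lower, 0.464) did not pass. The number of genes that differed from WT was 4506 at day 3 (2174 higher, 2332 lower) and 3303 at day 9 (1577 higher, 1726 lower).

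How far the knockout change was reversed was counted over the 7519 genes that differed between KO and WT. At day 1 SULF2 had gone from 966.8 ± 34.2 to 637.0 ± 33.9, MUC6 from 479.9 ± 17.2 to 289.7 ± 52.3 and H19 from 2034.8 ± 176.2 to 1042.8 ± 224.1. LGALS4 fell from 412.2 ± 31.2 to 237.9 ± 64.7 and BCL2 as above. Among lost genes, QPCT had risen from between 38.8 and 76.7 in the KO libraries to 100.5 ± 10.1. INTS6L, TSPOAP1, ZNF780B (8.3 ± 1.2) and CHRNA1 (4.7 ± 2.1) passed as well, the last 3 from 0 in all 3 KO libraries. By count, 1172 genes (15.6%) were called in the opposite direction at day 1, 663 raised in KO and now lower and 509 lowered in KO and now higher. The count fell to 693, 694 and 773 without KO replicate 1, 2 and 3. At days 3 and 9, which carry the other code, 3307 (44%) and 3516 (46.8%) genes were called in the opposite direction. Genes called further in the knockout's direction numbered 144, 141 and 44. In 20 draws, WT, KO and a doxycycline group set to the KO means were simulated, with the KO draws shared by both comparisons. They gave a median of 0 opposite calls (at most 1). With no difference between doxycycline and KO, few genes can pass that comparison, so the count does not measure overlap among passing genes. Independent lists of these sizes would share 224.3 and 185.6 genes (raised and lowered in KO) at day 1, 524.1 and 506.6 at day 3 and 504.5 and 468.1 at day 9. The covariance of the fold changes was -0.0935, -0.3459 and -0.3622 at days 1, 3 and 9, against simulated values of -0.0151, -0.0144 and -0.0145. The 3 KO libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls. Genes still called against WT in the knockout's direction numbered 5070, 3608 and 2927. The simulated median was 0 with the doxycycline group set to the WT means, where few genes can pass by design. The median share of the knockout effect recovered was taken over 1282 to 1328 genes changed by at least 1 log2 unit. It was 15.9% ± 1.7, 48.7% ± 0.7 and 52% ± 0.9 at days 1, 3 and 9 (SD over the 3 libraries of each time). By direction, the day 1 libraries spread more, at 18.7% ± 6.9 for genes raised in KO and 12.5% ± 3.4 for genes lowered. The shares and opposite calls at days 3 and 9 rest on the libraries of the other code, where the silent genes had the variance-to-mean ratio of 0.33 given above.

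The doxycycline times were also compared with each other, which tests whether their changes from KO differ. Between days 3 and 9, which share a project code, PHGDH, the first enzyme of serine synthesis, rose from 3276.4 ± 141.5 to 4682.8 ± 183.1 (0.52, adjusted p = 6.51e-06). NUPR1 rose from 42.3 ± 7.9 to 79.8 ± 7.5 and LGR5 from 588.0 ± 26.6 to 836.9 ± 47.0. KRT18 fell from 43244.9 ± 2068.1 to 28288.6 ± 1358.0 (-0.61), LCN2 from 562.2 ± 35.0 to 311.8 ± 19.4 (-0.85) and FER1L6 from 194.9 ± 15.9 to 91.8 ± 1.6 (-1.08). These examples were chosen after their values were seen. In all 1123 genes passed, 459 higher and 664 lower at day 9, and 46 changed by at least 1 log2 unit. The count was 627 and 672 without day 3 replicates 1 and 3, and 644 and 629 without day 9 replicates 2 and 3. Integrated stress response genes rose, 11 of 34 (15 with 1 lower adjusted over the list alone, median 0.19, camera adjusted p = 5.87e-08, adjusted p = 0.258 with an estimated correlation). Across the codes, 1113 genes differed between days 1 and 3 (605 higher, 508 lower at day 3, 737 without day 1 replicate 3 and 2026 without day 1 replicate 1). Between days 1 and 9, 1837 differed (893 higher, 944 lower at day 9). Fitting only the 6 libraries compared gave 426 and 853, and leave-one-out counts for days 1 and 9 ran from 1341 to 2699.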

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

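The tests of the values at days 3 and 9, of a difference of the knockout line and of doxycycline were chosen after the result was seen, as was the reading of a gene-order count on the edge of its range, and the fits had been run before any test was written down.

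Genes silent in KO stood at a median of 22.4% of WT at days 3 and 9, in 51 of 59 genes. The variance-to-mean ratio of these genes within a group was 0.33, which is less than counting reads alone gives and could come from an adjustment of the values between the 2 project codes before deposit. That explanation stays open, because the comparison genes of the same level were at 0.93 in WT and 0.91 in KO where 1 or more had been asked for, and such an adjustment could also enter the recovered shares and opposite calls of days 3 and 9. Over genes with a mean of at least 50, the log2 ratio of linear means of days 3 and 9 to the other groups had an SD of 0.113. This was the smallest of 10 pairings of groups (next 0.136), as values evened out between the codes would give. By the mean log2 difference the same pairing ranked 4 of 10 (SD 0.23, smallest 0.211), so the pairings did not decide. The 8 genes at 0 in all 6 libraries would argue against parental cells or reads mixed in, had the values been as counted. There 11.6 to 49.2 were predicted from the median share of the 51 genes. If the values were adjusted before deposit, these zeros cannot test mixing. Re-expression as the sole cause is argued against by the upper bound of the ratio, 0.49.

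The same 59 genes stayed near 0 at day 1, when USP7 was already above WT. Loss of a DNA segment holding several expressed genes is argued against for 51 of them. These had no silent gene among the 5 nearest expressed genes on either side. The 116 nearest expressed neighbours of the silent genes had a median log2 change of -0.03 (quartiles -0.31 and 0.21). Silent genes were left out of these neighbours, so a lost neighbour could not show there and the median adds no support. Loss of a segment holding 1 expressed gene cannot be tested this way and stays open for all 59. Loss of several genes together may explain part of the other 8, which had another silent gene among the 5 nearest expressed genes on either side, and stays open for these. That count lies on the edge of the central 95% range of 0 to 8 in 1000 random draws (median 2, as many in 4.9% of draws), where a count inside the range was to argue against a loss. A difference of the knockout line from its parental cells that USP7 does not control could also explain them and stays open, with 1 gene above 5% of WT at day 1.

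Gene lists changed at day 1 of doxycycline, and WT cells given doxycycline were not analysed here. Doxycycline acting on mitochondria apart from USP7 may raise the integrated stress response. The median log2 change of that list at day 1 was -0.06 (34 genes), with a 95% bootstrap interval over 2000 draws of genes, not libraries, from -0.1 to an upper bound of -0.03. The list had 16 genes higher and 5 lower in KO (median 0.2), so the return of USP7 could hide a rise, and this and other actions of doxycycline stay open. Nuclear oxidative phosphorylation (adjusted p = 0.00177) and mitochondrial ribosomal proteins (0.00125) passed camera at day 1, both opposite to their change in KO, and neither did with an estimated correlation (0.295 and 0.254).

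Against KO, the day 9 change differed from the day 3 change for several genes. USP7 differed by -0.71 log2 units between the times. TNC rose further, by 0.7. KRT13 fell further (-1.05), as did AQP3 (-1.1), AUTS2 (-0.65), SULF2 (-0.42) and PSCA (-1.29). The day 1 responders GSDMA (-0.4), RUFY3 (-0.3) and DHRS3 (-0.91) had come down by day 9. MUC6 went back up by 0.99. The change from KO differed for 1123 genes between days 9 and 3, for 1113 between days 3 and 1 and for 1837 between days 9 and 1. Between days 9 and 3 it differed for 11 gene lists, 4 upward and 7 downward, and for 0 by camera with an estimated correlation. By fry, which tests against no change, 7 of all tested lists passed.

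Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05. Every split but the real one mixes libraries of both groups. It keeps part of the real difference, which can let lists pass, and adds the rest to the spread, which lowers gene counts. Neither kind of count therefore measures chance alone, and the splits do not decide about it. In all 10 gene comparisons the real split was the only 1 of the 10 to reach its count. The real counts and the highest other split were 7519 and 0 for KO against WT, 1650 and 1 for day 1 against KO, 4149 and 0 for day 3 against KO and 3915 and 0 for day 9 against KO. They were 6158, 4506 and 3303 against 0 for days 1, 3 and 9 against WT. Between the times they were 1113 and 1 (days 3 and 1), 1123 and 0 (days 9 and 3) and 1837 and 290 (days 9 and 1). For gene lists the real count and the highest other were 8 and 11 for KO against WT, where 7 of 10 splits reached the real count. They were 17 and 14 at day 1 (1 of 10), 12 and 13 at day 3 (3 of 10), 14 and 13 at day 9 (1 of 10) against KO, and 8 and 8 for day 9 against WT (2 of 10).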

How the results depend on the processing

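The fits to the libraries of 1 project code, equal medians for named genes and lists, and the settings applied to reversal at days 1 and 3 are tests chosen after the result was seen. Of the values of the leading counts and recovered shares under other settings, 271 stayed within 1.5 times (1 SD between libraries for shares) and 47 did not. Among the shares 0 changed sign, which counts cannot do. For named genes 172 calls were lost and 2 gained, and 7392 values kept their state, which includes those past the threshold in neither fit. For lists 79 calls were lost and 58 gained, and 1573 values kept their state in the same sense. Most lists had no call to lose. Of 30 tested, 8 passed in the main fit for KO against WT and 17, 12 and 14 for days 1, 3 and 9 against KO. For day 9 against WT 8 passed. A count model, DESeq2 and RLE scaling were not run, because steps of the values close to 1 were treated as rounding and the values were not used as reads.

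Asking for at least 1 log2 unit left 1319 genes for KO against WT, 121, 497 and 497 for days 1, 3 and 9 against KO and 999, 540 and 450 for days 1, 3 and 9 against WT. It left 182, 46 and 254 between days 3 and 1, 9 and 3, and 9 and 1. Fitting only the 6 libraries compared gave 613 for day 1 against KO, 426 for days 3 and 1 and 853 for days 9 and 1. Fitting the 9 libraries of 1 code gave 7348 for KO against WT and 1305 for day 1 against KO, and the 6 of the other gave 1325 for days 9 and 3. With a replicate block the counts were 7936 for KO against WT and 1969 for day 1 against KO, although pairing is not stated and 8 of 15 libraries were closest to their own number.

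Leave-one-out counts ran from 6531 to 6677 for KO against WT, from 3219 to 3414 and 3003 to 3399 for days 3 and 9 against KO, and from 5193 to 6827, 3571 to 3870 and 2409 to 2963 for days 1, 3 and 9 against WT. For day 1 against KO they ran from 958 to 2418, with 984, 958 and 1058 without KO replicates 1, 2 and 3 and 1096 without day 1 replicate 3. Days 3 and 1 gave 737 (without day 1 replicate 3) to 2026 (without day 1 replicate 1). Days 9 and 3 gave 627 to 924, with 627 and 672 without day 3 replicates 1 and 3 and 644 and 629 without day 9 replicates 2 and 3. Days 9 and 1 gave 1341 to 2699. The USP7 change in KO ran from -1.29 to -1.28.

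Reversal with knockout changes of at least 1 log2 unit gave 286, 874 and 894 opposite calls and 1095, 874 and 806 calls still against WT at days 1, 3 and 9. Leave-one-out gave 693 to 1602 opposite calls at day 1 (693, 694 and 773 without KO replicates 1, 2 and 3), 2610 to 3059 at day 3 and 2730 to 3283 at day 9. Calls still against WT ran from 4313 to 5576, 2891 to 3347 and 2158 to 2721. The recovered share was 19, 52.6 and 55.6% with all 3 KO libraries on both sides of the ratio, and 19.5 and 45.2% at days 1 and 3 over knockout changes of any size. Leave-one-out shares ran from 15.2 to 16.3, 48 to 48.5 and 51.7 to 52.7%.

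With an estimated correlation, camera passed 2 lists for KO against WT, 3, 4 and 2 for days 1, 3 and 9 against KO and 0 for day 9 against WT. By fry, 19 passed for KO against WT, 22 for day 3 against KO and 14 for day 9 against WT. Leave-one-out list counts ran from 8 to 9, 10 to 17 (10 without day 1 replicate 1), 11 to 14, 13 to 15 and 8 to 9 in the same order. Some lists passed camera only with 1 library left out. Against KO these were immediate early genes at day 1 (lowest adjusted p = 0.0141), E2F (0.021) and FOXO targets (0.021) at day 3, and hypoxia (0.0153) and integrated stress response genes (0.0423) at day 9. For day 9 against WT they were mtDNA-encoded genes (0.0172), histones (0.00634) and FOXO targets (0.0339). Equal medians moved the median fold change by at most 0.018 log2 units, and the share of higher calls from 48.9 to 52.9% for day 1 against WT, 48.2 to 51.1% for day 3 against WT and 48.6 to 41.8% for days 9 and 1. That share went from 45.3 to 49.6% for day 1 against KO, 54.4 to 50.8% for days 3 and 1 and 40.9 to 36.6% for days 9 and 3. It moved less in the other comparisons.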

Other observations

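The examples here were picked and the tests chosen after the result was seen. Some genes rose between days 3 and 9, and PHGDH, lowered in KO, rose mainly then. PHGDH, which starts serine synthesis, stood at 5048.3 ± 188.8 in WT and 3218.1 ± 60.4 in KO, and at 3211.6 ± 331.5, 3276.4 ± 141.5 and 4682.8 ± 183.1 at days 1, 3 and 9. The stress response gene NUPR1 (82.1 ± 4.8 in WT, 42.3 ± 7.9 at day 3, 79.8 ± 7.5 at day 9) rose between the same times. So did the growth factor gene BMP4 (9318.5 ± 261.4, 7226.2 ± 49.3 and 9017.9 ± 233.8). Against WT, BMP4 stood at -0.59 log2 units at day 1 and -0.37 at day 3, so part of its rise came earlier, across the codes. Days 3 and 9 share a project code, and between them PHGDH changed by 0.52 (adjusted p = 6.51e-06), NUPR1 by 0.91 (0.00666) and BMP4 by 0.32 (6.7e-05).

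Other genes moved against the reversal at day 1 or lay in lists that did not pass. TGFB2, which encodes a TGF-beta ligand, fell from 558.5 ± 17.4 in WT to 56.1 ± 15.3 in KO and further to 25.1 ± 6.6 at day 1 (log2 change -1.13, adjusted p = 0.000608). At days 3 and 9, under the other project code, it stood above KO at 156.2 ± 12 and 181.2 ± 3.4. SAMD9L was raised in KO (12.3 ± 0.6 to 41.2 ± 3.5) and raised again at day 1, to 68.8 ± 5.8 (0.73, adjusted p = 0.00372), unlike SAMD9. Imprinted genes changed in KO both ways, 5 of 11 higher and 3 lower (camera adjusted p = 0.367): the cell cycle inhibitor CDKN1C rose from 81.1 ± 3.3 to 230.0 ± 11.4 and MEST from 1015.8 ± 40.0 to 1645.6 ± 60.4, while the growth factor gene IGF2 fell from 39.2 ± 5.5 to 1.3 ± 0.6. Of 21 heat shock genes, 9 rose and 6 fell (median 0.04, mean -0.06, adjusted p = 0.906), with the chaperone gene HSPH1 down from 4856.1 ± 62.7 to 1033.5 ± 24.0 and FKBP4 up from 2257.7 ± 28.8 to 3789.1 ± 212.8. Of 34 cholesterol and fatty acid genes, 16 rose and 5 fell (median 0.12, mean -0.1, adjusted p = 0.26), the desaturase gene FADS2 falling from 447.6 ± 18.5 to 131.1 ± 10.6.

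MYC targets and interferon genes changed at day 1 against KO in the direction opposite to the KO change, and both passed with an estimated correlation in both comparisons, while mitotic genes did not pass at day 1. A candidate explanation is that MYC and interferon genes may follow USP7 within a day and mitotic genes later, which these data cannot separate from the project code at days 3 and 9. Mitotic genes had a median log2 change of 0 at day 1 (adjusted p = 0.792). Cells of the same knockout line sampled at several times under 1 project code, beside WT cells given doxycycline, would test this.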
